A study of Mus musculus with 6 samples.

How the data were processed

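RNA was isolated from heart with a silica column kit, 50 ng was amplified with a whole-transcriptome kit, and 5 µg of amplified cDNA was labelled with Cy3, per the labels' protocols. Each sample was hybridised to an Agilent 1-colour array whose probes were designed on the mm7 mouse assembly, and scans were read by Feature Extraction 9.5.3.1 with the protocol GE1-v5_95_Feb07, per the file headers (version 9.5 per the submitters' processing notes). The deposited processed signal of each spot is an intensity on a linear scale, background-subtracted and spatially and multiplicatively detrended within its array, per the file headers, and is not normalized between arrays. Low intensities are replaced by a surrogate value in the deposited files, which held for 15.3% to 22.0% of noncontrol spots. The deposited value table held the same intensity as the scanner files for all 45018 spots of each array, so its scale is linear, it is not centred, and its column medians were 70.8, 68.1 and 84.4 for the sham and 75.1, 92.2 and 80.9 for the adrenalectomized samples.

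Groups were taken from the sample labels, which name 3 sham-operated and 3 adrenalectomized mice, and the design text calls them biological replicates. The protocol places surgery at 1 month of age and collection 6 months later, whereas another label calls the mice 6 months old, so the age at collection is uncertain by about the age at surgery. The design, the gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined.

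Processed signals were taken as log2, the 75th percentile of each array was subtracted, control spots and outlier-flagged spots (80 to 133 per array) were left out, and repeat spots of a probe were averaged. Of 41174 noncontrol probes, 22951 (55.7%) were named through a RefSeq accession in a table of current mouse genes, which updated 5141 symbols, and 18223 kept the name in the scanner file, for 28786 gene names. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which left 23989 probes, and a gene was represented by its tested probe with the highest mean, giving 16948 genes, of which 3624 had a clone or accession name. Where a gene was not well above background with any probe on every array of a group, its fold was given as a bound. A p-value printed beside a bound, in any fit, belongs to the fitted difference, which uses the dim signals. The bounds themselves were not tested. The bound sets the mean of the other group against the mean of, per array, the higher of the lowest signal among probes well above background and the signal of the dim probe itself. Coordinates are those of the array design on mm7, counted from 1.

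Differences (adrenalectomized minus sham) were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 31 gene lists held 568 members, 556 of them on the array, and lists with at least 3 measured members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Camera asks whether the genes of a list shifted more one way than the other genes. With the preset correlation, its p-value does not measure the spread between mice. Besides the lists of heart function, metabolism, stress and steroid action, lists of markers of other cell types were included, and all 31 are reported. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the figures.

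Genes were named by a fixed rule: per direction up to 10 genes of largest change among those past the threshold with non-overlapping groups, filled to 5 by smallest p where fewer passed; steroid-responsive and cardiac stress genes whatever their result; from each list the members past the threshold or, failing that, the 2 of smallest p; and the 5 genes per direction with the largest bound. Genes with clone or accession names were not named by the first part. Some genes that the rule or a list names are not reported here. Zbtb16, one of the steroid-responsive genes, matched no probe by name and was not analysed here. Other list members and genes named as examples, such as Mki67, Ccna2, Cdk1, Birc5, Ccnd1, Ccnd2 and Bmp10, were chosen after their values were seen.

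Alternatives were normexp background correction (offset 50) on the mean spot and local background intensity, quantile normalization, median centring, a 75th percentile over detected probes, the deposited value table, other filters on dim probes, the mean of the probes of a gene, every probe tested, outlier spots kept, the slide as a fixed or random block, slide 1 alone, the replicate number as a block, a variance trend with robust estimation, array weights, each array left out, and other thresholds. Normexp fitted on the negative control spots was added after seeing the data. The scan batches were the same as the slides, so the slide stands for both.

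The fit was tested on simulated data with 200 of 16948 genes changed for the comparison of adrenalectomized against sham. Of 50 genes changed by each size, 30 were called at a log2 change of 1, 49 at 2, 48 at 3 and 50 at 4, all with the right sign, with 13 false calls. The proliferation list, shifted by a log2 of 0.5, passed the set test, as did 1 list that was not shifted. Noise was drawn independently for each gene, with no slide effect and no link between genes. These shares therefore do not carry over to the real arrays.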

Results

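Heart RNA of 6 male C57BL/6 mice, a common inbred laboratory strain, was measured on 1-colour Agilent arrays of 60-base probes, with 1 array per heart. The mice had either been adrenalectomized, which removes the adrenal glands and with them the main source of corticosterone and aldosterone, or had undergone a sham operation, at 1 month of age, and their hearts were taken 6 months later. Each group held 3 biological replicates. The share of spots well above background was 59.8%, 57.7% and 60.2% on the sham arrays and 60.5%, 66.8% and 63.2% on the adrenalectomized arrays, and the 75th percentile of the processed signal ran from 644 to 924 intensity units. Log2 values of any 2 arrays correlated across genes at a Pearson r of 0.982 or more, where genes are not independent replicates. The number of arrays limits the precision, with a median standard error (SE) of 0.14 on the log2 scale for the difference between groups. The sham arrays and adrenalectomized replicate 1 lay on slide 1, and adrenalectomized replicates 2 and 3 lay on slide 2. Because slide 2 held no sham array, a difference with the slide as a block is the difference within slide 1, where a single adrenalectomized array stands against the 3 sham arrays and is assumed to vary as they do.

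The comparison asks what long-term loss of the adrenal glands does to gene expression in the heart, within a series on the part of glucocorticoids in cardiac homeostasis. Klk1b16 and Egfbp2, which belong to the tissue kallikreins, a family of serine proteases encoded in a cluster on chromosome 7, gave lower signal in adrenalectomized hearts, and the list of proliferation genes was higher as a group (12 of 12 members higher, camera adjusted p = 3.59e-10; adjusted p = 0.386 with an estimated correlation). Over all genes, 1 of the 12 passed. Of 16948 genes tested, 5 rose and 2 fell at a Benjamini-Hochberg adjusted p under 0.05 in limma. The 5 that rose were Ccnb1 (cyclin B1, which drives entry into mitosis), Cdca5 (sororin, which holds sister chromatids together), Brca1 (repair of double-strand breaks), E2f1 (a transcription factor of S-phase genes) and Rnf186 (a ubiquitin ligase). For each of these 7 genes, all 3 adrenalectomized values lay on one side of all 3 sham values.

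Klk1b16 had a log2 level of -2.90 ± 0.19 (SD, n = 3) relative to the 75th percentile of the array in sham hearts. It was not well above background on any of the 3 adrenalectomized arrays, a drop of at least 3.47-fold. The limma adjusted p of 0.00208 belongs to its fitted difference of -3.74, which uses those dim signals, and not to the bound. Egfbp2 changed from -1.44 ± 0.16 to -3.07 ± 0.14 (SD, n = 3), a log2 difference of -1.63 (SE 0.13) or 3.09-fold (limma adjusted p = 0.0438). Another pair of kallikreins narrowly missed the threshold. Klk1b26 was at least 5.05-fold lower (fitted difference -3.63) and Klk1b5 differed by -1.64 (SE 0.18), with a limma adjusted p of 0.0587 for each fitted difference. Wif1, a secreted inhibitor of Wnt signalling, differed by -0.86 (SE 0.10) at the same adjusted p of 0.0587. The kallikrein genes are near-identical copies, so which family member each probe read is uncertain. Klk1b16 kept its call in 21 of 22 alternatives, and Egfbp2 in 12 of 23. With an array left out, Egfbp2 passed only without adrenalectomized replicate 1. In the fit with the slide as a block, Klk1b16 passed (at least 2.98-fold lower within slide 1, adjusted p = 0.0341) and Egfbp2 differed by -1.63 (adjusted p = 0.204). In design coordinates of the mm7 mouse assembly, the probes lie on chromosome 7 from 40315381 to 40315440 for Klk1b16, from 40190180 to 40190608 for Egfbp2, from 40189980 to 40190135 for Klk1b26 and from 40394484 to 40394542 for Klk1b5. A gene annotation of mm7 was not used here, so the exon or untranslated region of each probe is not given.

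Among the genes that rose, Cdca5 changed from -2.74 ± 0.11 to -1.64 ± 0.07 (SD, n = 3), a log2 difference of 1.10 (SE 0.11) or 2.15-fold. E2f1 was 2.45-fold higher, a log2 difference of 1.29 (SE 0.13), and was above background on 2 of the 3 sham arrays. Ccnb1, Rnf186 and Brca1 were not well above background on any sham array, and rose by at least 1.28-fold, 1.66-fold and 1.64-fold. Their fitted differences of 2.31, 1.58 and 1.20 use the dim sham signals, and their limma p-values belong to these and not to the bounds. With only probes above background on all 6 arrays, 0 genes rose. That filter removes Ccnb1, Rnf186, Brca1 and E2f1 from the test, so of the genes that rose it retested only Cdca5. All 5 genes of the main fit had a limma adjusted p of 0.0487. Their probes lie on mm7 chromosome 13 from 97885282 to 97885341 (Ccnb1), chromosome 4 from 138346565 to 138346624 (Rnf186), chromosome 19 from 5986515 to 5986574 (Cdca5), chromosome 11 from 101598134 to 101598193 (Brca1) and chromosome 2 from 154301126 to 154301185 (E2f1). Blocking on the slide gave differences of 1.03 for Cdca5 and 1.41 for E2f1, and bounds within slide 1 of at least 1.10-fold for Ccnb1, 1.60-fold for Rnf186 and 1.78-fold for Brca1, each at an adjusted p of 0.204.

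**Figure D1:**
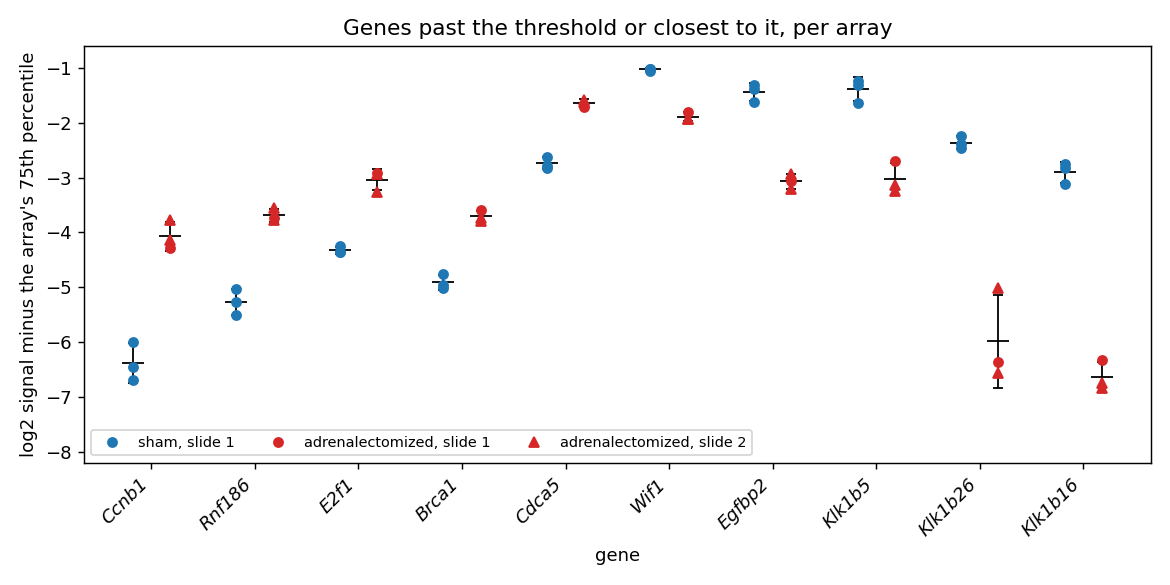
Log2 processed signal minus the 75th percentile of the array (vertical axis) for the 5 genes that rose, the 2 that fell and the 3 lower genes of next smallest p, with 1 point per array, circles for slide 1, triangles for slide 2, and bars for the mean and SD of each group (n = 3). Points of Ccnb1, Rnf186 and Brca1 in sham hearts and of Klk1b16 and Klk1b26 in adrenalectomized hearts were not well above background, and the groups do not overlap for any of the 10 genes.

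The calls were few against the number of nominal differences. At an unadjusted p under 0.05 there were 1062 higher and 1016 lower genes, 2078 in all, where 847 would be expected by chance, and the values of the groups did not overlap for 18.3% of genes, where chance gives 10%. The split that sets sham replicates 1 and 2 and adrenalectomized replicate 3 against the other arrays gave more, 2158 genes at an unadjusted p under 0.05, and 0 past the threshold. The count depended on the scaling, with 2 higher and 3 lower genes after quantile normalization and 0 higher and 2 lower genes both after median centring and with a 75th percentile over detected probes. With the slide as a block, 0 genes rose and 1 fell, with 1689 genes at an unadjusted p under 0.05. Omission of single arrays gave from 0 to 39 higher genes, the most without adrenalectomized replicate 1, and from 1 to 6 lower genes, the most without sham replicate 2. Normexp background correction on the local background gave 1220 higher and 4730 lower genes and turned the direction of the fitted difference of Ccnb1 (-0.87), Rnf186 (-0.87), Brca1 (-1.15) and E2f1 (-0.55), of which the first 3 passed the other way. It left Cdca5 without a difference (0.00019, adjusted p = 0.999), and the mean of its probes gave Cdca5 0.69 (adjusted p = 0.337). After normexp on the local background, the 10th percentile of the signal was 422, 154 and 553 on the sham arrays. On the adrenalectomized arrays it was 147, 73.3 and 80.8. An exact permutation test of a single gene cannot give a two-sided p below 0.1 with 3 against 3 arrays.

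None of the 8 measured genes named in advance as readouts of steroid action passed the limma test over all genes, and none had an unadjusted p under 0.05. Normexp background correction called Fkbp5 (-0.84) and Nr3c2 (-1.11) lower. It called 4730 of all 16948 genes lower, so these 2 calls do not single out the steroid-responsive genes. Fkbp5, a chaperone induced by the glucocorticoid receptor, differed by -0.31 (SE 0.21, adjusted p = 0.588), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, by -0.25 (SE 0.12, adjusted p = 0.451). The differences were -0.19 for the kinase gene Sgk1, -0.17 for the transcription factor gene Klf9, -0.06 for the clock gene Per1 and -0.0018 for Klf15. The glucocorticoid receptor gene Nr3c1 differed by 0.07 (adjusted p = 0.880) and the mineralocorticoid receptor gene Nr3c2 by -0.42 (adjusted p = 0.692). As a group, the 23 measured glucocorticoid-induced genes had a median log2 difference of -0.17 and were lower in limma's camera set test (adjusted p = 0.00849; adjusted p = 0.667 with an estimated correlation). Of these, 18 had lower values and 5 higher, and 0 passed either over all genes or adjusted over the list alone, while 2 higher and 4 lower members had an unadjusted p under 0.05. Glul, glutamine synthetase, differed by 0.53 (SE 0.12, adjusted p = 0.226), and the transcription factor gene Cebpd by -0.43 (SE 0.12, adjusted p = 0.264). The probes of some of these genes disagreed, and the mean over probes turned Glul to -0.03 (adjusted p = 0.937), Nr3c1 to -0.24 and Klf15 to 0.13. The call was lost with the slide as a block (median within slide 1 of -0.10, adjusted p = 0.243) and without sham replicate 2 (adjusted p = 0.0510), sham replicate 3 (0.0927) or adrenalectomized replicate 3 (0.0965). With an array left out, the median ran from -0.26 to -0.06. It was lost too without a filter on dim probes (0.0615) and with array weights (0.115).

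The proliferation list rose as a group, with all 12 measured members higher in adrenalectomized hearts and a median log2 difference of 0.61, or 0.54 with Ccnb1 at its bound. Over all genes 1 member passed and 11 did not, and adjusted over the list alone 8 rose, 0 fell and 4 did not pass. Among the 8 were Mki67, a marker of cycling cells, at 1.04, Ccna2 (cyclin A2) at 1.04, Cdk1 (the mitotic kinase) at 1.20 and Birc5 (survivin) at 0.83. The G1 cyclins Ccnd1 and Ccnd2 differed by 0.17 and 0.02 and did not pass. The camera adjusted p was 3.59e-10 (adjusted p = 0.386 with an estimated correlation), and fry, which tests whether genes of a list move on balance one way, gave an adjusted p of 0.0210. Blocked by slide, the list still passed (adjusted p = 7.44e-06), and the median was 0.72 within slide 1, or 0.56 with Ccnb1 at its bound. Normexp background correction ended the call (adjusted p = 0.126, median 0.31). Per array, the median distance from the sham mean was 0.72, 0.65 and 0.62 on the adrenalectomized arrays and between -0.05 and 0.09 on the sham arrays.

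Atrial markers fell as a group, with all 12 measured members lower and a median of -0.65 (camera adjusted p = 3.59e-10; adjusted p = 0.452 with an estimated correlation). None passed over all genes, and adjusted over the list alone 9 fell and 3 did not pass. Pam, the peptide-amidating enzyme abundant in atrial granules, differed by -1.07 (SE 0.21, adjusted p = 0.195 over all genes), and Stard10, a lipid transfer protein, by -0.55 (SE 0.13, adjusted p = 0.239). The atrial natriuretic peptide gene Nppa differed by -0.70, the atrial growth factor gene Bmp10 by -1.37, the atrial light chain genes Myl4 and Myl7 by -0.50 and -0.53, and sarcolipin (Sln) by -0.61. The list passed with the slide as a block (adjusted p = 7.44e-06), with a median of -0.59 within slide 1. It lost its call with normexp background correction (adjusted p = 0.253, median -0.29) and with fry (adjusted p = 0.175). Fetal and hypertrophy genes, which share Nppa, Myl4 and Myl7 with the atrial list, were lower too (median -0.36 over 15 members, camera adjusted p = 0.000251; adjusted p = 0.657 with an estimated correlation). In that list 5 members fell adjusted over the list alone and 0 over all genes, among them Nppa and Tnni1 (slow skeletal troponin I of the fetal heart, -0.45, SE 0.13, adjusted p = 0.269 over all genes). Nppb, Myh7 and Myh6, the genes of brain natriuretic peptide and of the beta and alpha myosin heavy chains, differed by -0.24, -0.46 and -0.17 and did not pass (adjusted p = 0.802, 0.365 and 0.707). The fetal list passed with the slide as a block (adjusted p = 0.00766), with a median of -0.37 within slide 1. Normexp background correction ended that call (adjusted p = 0.874), as did fry (adjusted p = 0.311).

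Immediate early genes, which respond within minutes to stimulation or tissue handling, were lower as a group, with 12 of 15 members lower and a median of -0.51 (camera adjusted p = 0.000251; adjusted p = 0.667 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and 5 lower members had an unadjusted p under 0.05. The nuclear receptor genes Nr4a1 and Nr4a2 differed by -1.73 (SE 0.54, adjusted p = 0.300) and -1.03 (SE 0.33, adjusted p = 0.306). The list passed with the slide as a block (adjusted p = 6.73e-05), with a median of -0.69 in that fit and -0.53 on slide 1 alone (adjusted p = 0.00411), where the filter on dim probes used its 4 arrays. The call was lost with normexp background correction (adjusted p = 0.183, median -0.35) and with fry (adjusted p = 0.492). Per array the medians were 0.53, -0.47 and 0.02 on the sham arrays and -0.69, -0.42 and -0.38 on the adrenalectomized arrays. Sham replicate 2 thus lay below 2 of the adrenalectomized arrays, and without sham replicate 1 the median shift was -0.30.

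Adipocyte markers were higher as a group, with all 13 measured members higher and a median of 0.94 (camera adjusted p = 0.000337; adjusted p = 0.671 with an estimated correlation). No member passed over all genes or adjusted over the list alone, while 4 had an unadjusted p under 0.05. Ucp1, the uncoupling protein of brown fat, differed by 2.88 (SE 0.82, adjusted p = 0.274), and Plin1, which coats lipid droplets of adipocytes, by 1.79 (SE 0.68, adjusted p = 0.375). The per-array medians were spread within groups, at -1.12, 0.50 and 0.18 on the sham arrays and 0.04, 1.95 and 1.22 on the adrenalectomized arrays. The call was lost with the slide as a block (adjusted p = 0.983), and the median within slide 1 was 0.04. Erythroid and platelet markers had a median of 0.65 over 8 members and did not pass (camera adjusted p = 0.106), with Itga2b at 0.76 and Slc4a1 at 0.92. Blocked by slide, that list passed (adjusted p = 0.0336, median 1.03), and its medians on the adrenalectomized arrays were 1.03, 1.29 and -0.50. The erythroid list passed in 8 of 25 alternatives, among them omission of adrenalectomized replicate 3 (2.22e-09), and with an array left out its median ran from 0.26 to 1.18. Lymphocyte markers had a median of 0.36 over 14 members and did not pass (adjusted p = 0.0559), with Dntt at 0.86 and Cd3g at 0.33, and a median of -0.0096 with the slide as a block. The list passed in 10 of 25 alternatives, among them median centring (0.0481) and omission of sham replicate 2 (0.0124), adrenalectomized replicate 1 (0.0352) or adrenalectomized replicate 3 (0.0177). Its medians on the adrenalectomized arrays were -0.01, 0.83 and 0.16.

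Interferon response genes were slightly higher as a group, with 21 of 22 members higher and a median of 0.17 (camera adjusted p = 0.00947; adjusted p = 0.754 with an estimated correlation). The median of sham replicate 2 was 0.33, above the 0.15, 0.19 and 0.17 of the adrenalectomized arrays, and without sham replicate 3 the median shift was 0.03. Rsad2 (viperin) differed by 0.62 and Irf7, a regulator of interferon genes, by 0.46, without passing. Small group shifts in the other direction were found for adrenergic signalling (median -0.11 over 18 members, adjusted p = 0.00581; adjusted p = 0.452 with an estimated correlation) and for ion channels and conduction (median -0.13 over 22, adjusted p = 0.00771; adjusted p = 0.671 with an estimated correlation). Npy1r (a neuropeptide Y receptor) and Chrm2 (the cardiac muscarinic receptor) differed by -0.86 and -0.62, and Atp1b1 (a sodium pump subunit) and Kcnj3 (an atrial potassium channel) by -0.47 and -0.41, all 4 without passing. Sarcomere genes (median -0.16 over 20, adjusted p = 0.0127; adjusted p = 0.671 with an estimated correlation) included Myom1 at -0.35 and Tnni3 at -0.29. Oxidative phosphorylation genes (median -0.11 over 24, adjusted p = 0.0131; adjusted p = 0.754 with an estimated correlation) included Cox6a2 at -0.32 and Ndufa4 at -0.24. Extracellular matrix and fibrosis genes (median -0.17 over 24, adjusted p = 0.0473; adjusted p = 0.671 with an estimated correlation) included Ccn2 at -0.59 and Col3a1 at -0.34. In these 6 lists 0 members passed in limma over all genes or adjusted over the list alone, where the members with an unadjusted p under 0.05 numbered 4 for interferon, 3 for adrenergic, 6 for ion channel, 2 for sarcomere, 1 for oxidative phosphorylation and 4 for matrix genes.

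The slide block ended the call for interferon (adjusted p = 0.243, median 0.15 within slide 1), adrenergic (0.0568, -0.07), ion channel (0.799, 0.04), sarcomere (0.799, -0.03) and oxidative phosphorylation genes (0.996, 0.01), and the matrix genes passed (0.0336, -0.22). Scaling moved some of these calls too. After quantile normalization the adjusted p was 0.388 for sarcomere, 0.763 for oxidative phosphorylation and 0.0608 for matrix genes, and with the 75th percentile over detected probes it was 0.0516 for matrix genes. On adrenalectomized replicates 1, 2 and 3 the medians were -0.03, -0.18 and -0.17 for sarcomere, 0.04, -0.20 and -0.25 for ion channel and 0.01, -0.17 and -0.18 for oxidative phosphorylation genes, beside 0.04, 1.95 and 1.22 for adipocyte markers. Whether more fat in replicates 2 and 3 lowered these lists was not tested. Single arrays decided some calls as well. Omission of sham replicate 1 ended the call for interferon (adjusted p = 0.102) and oxidative phosphorylation genes (0.112), of sham replicate 2 for matrix genes (0.0863), and of sham replicate 3 for matrix (0.544) and interferon genes (0.278). Omission of adrenalectomized replicate 1 did so for matrix genes (0.0896), of replicate 2 for sarcomere (0.131), oxidative phosphorylation (0.0770) and interferon genes (0.0504), and of replicate 3 for sarcomere (0.0579), oxidative phosphorylation (0.165) and ion channel genes (0.0516). The proliferation, atrial, fetal, immediate early, adipocyte and adrenergic lists passed without any single array. The size of the shift was less stable, with medians from 0.58 to 1.48 for adipocyte, -0.80 to -0.30 for immediate early and -0.15 to -0.06 for adrenergic genes. Over the 25 alternatives of each list, the call was not kept in 2 for proliferation, 3 each for atrial, fetal and immediate early, 4 for adipocyte, 6 each for adrenergic and ion channel, 7 for interferon, 9 for sarcomere, 10 for glucocorticoid-induced, 11 for oxidative phosphorylation and 15 for matrix genes. Normexp background correction turned the set test upward for sarcomere (adjusted p = 0.0011) and oxidative phosphorylation genes (adjusted p = 0.000574). In all, 12 of the 31 lists passed camera with its preset correlation, 3 higher and 9 lower, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. For adrenergic genes the estimated correlation was 0.018, near the preset 0.01, yet the camera adjusted p went from 0.00581 to 0.452. The loss of calls with an estimated correlation therefore cannot be read as the work of linked genes alone. The small camera p-values with the preset correlation compare genes with genes and do not measure the spread between mice.

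**Figure D2:**
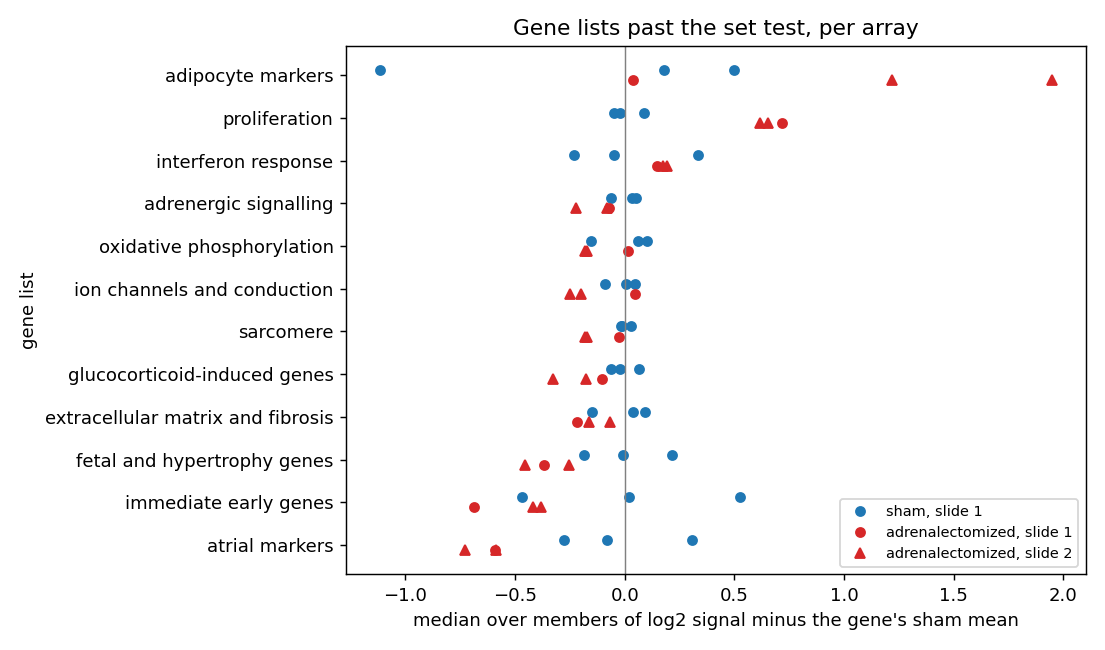
Median over the members of each gene list of the log2 signal minus the sham mean of the gene (horizontal axis) for the 12 lists past the camera test (vertical axis), with 1 point per array, circles for slide 1 and triangles for slide 2. Proliferation genes on the 3 adrenalectomized arrays lie at 0.72, 0.65 and 0.62, above all sham arrays, while adipocyte markers range from -1.12 to 0.50 on the sham arrays and from 0.04 to 1.95 on the adrenalectomized arrays.

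Calcium handling genes did not pass, with a median of -0.00048 over 18 members (camera adjusted p = 0.372, 0.0413 without adrenalectomized replicate 1, and 0.0346 with every probe tested), and 1 of them, Cacna2d1, a calcium channel subunit, fell adjusted over the list alone, with a difference of -0.96 (SE 0.11, adjusted p = 0.0587 over all genes). Sln, in that list too, differed by -0.61. Fatty acid oxidation genes had a median of -0.03 over 24 members (adjusted p = 0.453), with the lipid droplet protein gene Plin2 at 1.01 and the coactivator gene Ppargc1a at -0.86. Glucose uptake and glycolysis genes had a median of -0.05 over 22 members and a mean of 0.03, with a camera direction of lower (adjusted p = 0.620), and included Eno1 at 0.79 and Ldhb at -0.21. Steroid receptor and renin-angiotensin genes had a median of -0.07 over 8 members (adjusted p = 0.620), with angiotensinogen (Agt) at -1.30 (SE 0.46) and the sodium channel subunit gene Scnn1a at 1.12 (SE 0.44). The circadian clock genes had a median of 0.07 over 16 members and a mean of 0.0059 but a camera direction of lower (adjusted p = 0.887), with Nr1d1 at -0.39 and Arntl at -0.61.

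Inflammatory cytokines and adhesion molecules did not pass, with a median of 0.02 over 18 members (camera adjusted p = 0.817), and the interferon-induced chemokine gene Cxcl9 rose adjusted over the list alone, with a difference of 0.57 (SE 0.12, adjusted p = 0.206 over all genes). Cxcl10 differed by 0.74 (SE 0.29). Oxidative stress response genes had a median of 0.11 over 20 members (adjusted p = 0.817), with Gpx3 at -0.35 and Prdx1 at 0.34, and heat shock and unfolded protein response genes 0.05 over 18 (adjusted p = 0.933), with Hsph1 at 0.36 and Hspa1a at -0.33. Apoptosis and survival genes had a median of 0.0078 over 21 members (adjusted p = 0.901), with Bcl6 at 0.61 and Ccn2 at -0.59. Protein degradation and autophagy genes had a median of 0.0053 over 19 members and a mean of 0.03 with a camera direction of lower (adjusted p = 0.998), and included Bnip3 at 0.48 and Lamp2 at 0.26.

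Endothelial markers did not pass, with a median of -0.15 over 13 members (camera adjusted p = 0.0749, 0.0271 without adrenalectomized replicate 3, and 0.0159 with every probe tested), with Vwf at -0.64 and Tek at -0.26 (0.01 for the mean of its probes). Smooth muscle and pericyte markers had a median of -0.04 over 13 (adjusted p = 0.332), with Tagln at -0.69 and Abcc9 at 0.35, and fibroblast and epicardial markers -0.03 over 13 (adjusted p = 0.114), with Dcn at -0.32 and Gsn at -0.25. Macrophage and myeloid markers had a median of -0.10 over 18 (adjusted p = 0.0781, or 0.0102 without adrenalectomized replicate 2), with Cx3cr1 at -0.49 and Itgam at -0.33, and neutrophil and mast cell markers -0.16 over 7 (adjusted p = 0.160), with Cma1 at -0.22 and S100a9 at -0.29. Skeletal muscle markers had a median of -0.18 over 13 (adjusted p = 0.106). Of these, Tnni2 (fast troponin I) fell adjusted over the list alone, with a difference of -1.15 (SE 0.23, adjusted p = 0.197 over all genes), and Actn3 differed by -0.39. Neural and Schwann cell markers had a median of 0.14 over 10 (adjusted p = 0.911), with S100b at 0.79, and with the slide as a block this list was lower (adjusted p = 0.0336, median -0.26 within slide 1).

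Some genes were above background in a single group. There were 164 genes above background on all adrenalectomized arrays and no sham array, and 6 with the reverse pattern, while adrenalectomized replicates 2 and 3 also had the highest shares of spots above background. By lower bound, the leading genes on the adrenalectomized side were Elovl3 (a fatty acid elongase abundant in brown fat, at least 14.4-fold), Calml3 (a calmodulin-like protein of epithelia, at least 3.71-fold), Tff2 (a trefoil peptide of mucosa, at least 2.84-fold), Foxa1 (a transcription factor of endodermal epithelia, at least 2.42-fold) and Capsl (at least 2.33-fold). These bounds lean on part of the arrays. For Elovl3, adrenalectomized replicates 2 and 3 had log2 levels of 0.83 and 0.65 against -3.16 on replicate 1. Replicate 1 was also the lowest of the 3 for Calml3 (-4.36, group mean -2.53), Tff2 (-4.01, group mean -2.92) and Capsl (-3.88, group mean -3.21). Foxa1 had -3.32, -3.54 and -2.36. None of these 5 passed the limma test (adjusted p = 0.202, 0.241, 0.284, 0.270 and 0.230). On the sham side the kallikreins led, followed by Cep68, a centrosome protein, at least 1.91-fold lower in adrenalectomized hearts (adjusted p = 0.0860).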

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

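Of the alternatives, normexp on the negative control spots was chosen after seeing the data. The 5 genes higher in adrenalectomized hearts became 1220 with normexp on the local background, 0 with normexp on the negative control spots, 2 after quantile normalization, 0 with median centring, 0 with a 75th percentile over detected probes, 0 without a filter on dim probes, 0 with probes above background on all 6 arrays, 0 with the mean of the probes of a gene, 0 with every probe tested, 0 with outlier spots kept, 0 with the slide as a fixed block, 41 within slide 1, 6 with a variance trend and robust estimation, 38 with array weights and 23 at an adjusted p under 0.1. The 2 genes lower in adrenalectomized hearts became 4730, 0, 3, 2, 2, 1, 1, 2, 1, 2, 1, 2, 7, 37 and 11 in the same order. Where limma called 0 genes in all, with normexp on the negative control spots, 1901 had an unadjusted p under 0.05. The value table, the slide as a random block (consensus correlation -0.035) and a requirement of at least 1.5-fold gave 5 and 2. Of the 7 genes, 2 were still called in the same direction with normexp on the local background and 3 in the other. The same direction held for 4 after quantile normalization, 2 with median centring, 3 with a variance trend and 7 with array weights. With an array left out, it held for 1 to 3 of the 7. Leaving out an array moved the counts of higher and lower genes to 0 and 2 without sham replicate 1, 1 and 6 without sham replicate 2, 0 and 1 without sham replicate 3, 39 and 3 without adrenalectomized replicate 1, 0 and 2 without adrenalectomized replicate 2, and 3 and 1 without adrenalectomized replicate 3, with ranges of 0 to 39 and 1 to 6. Whether the smaller number of arrays or the array left out accounts for the lost calls was not tested, nor was the cause of the added calls.

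The count of 12 gene lists past the set test became 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. It was 1 with fry and 7 with the slide as a fixed block. Slide 1 alone apart, it was 9 to 13 in all other alternatives, and 9 to 13 with an array left out. The lists counted are not always among the 12. The 7 include erythroid and platelet markers and, turned to lower, neural and Schwann cell markers. The 11 with normexp on the local background include lists that passed in the turned direction and lists that newly passed, given below. The steroid-responsive genes named in advance numbered 0 past the threshold in all alternatives but normexp on the local background, where 2, Fkbp5 (-0.84) and Nr3c2 (-1.11), were among the 4730 genes called lower. Deviations from the group means of same-numbered arrays correlated at 0.158, 0.163 and -0.161. Of the adrenalectomized arrays, replicate 3 correlated best with sham replicate 2 (0.178). With 3 arrays per group, such correlations cannot decide whether the replicate numbers pair the samples. A fit with the replicate number as a block gave 0 higher genes, 1 lower gene and 12 lists.

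Normexp on the local background turned the direction of many results. The lowest signal minus background was -14080 on sham replicate 1 and -11550 on sham replicate 3, and the 10th percentile after correction was 422, 154 and 553 on the sham arrays against 147, 73.3 and 80.8 on the adrenalectomized arrays. Fitted without the 1566, 1292, 1164, 1197, 0 and 15 spots under their local background, in the same order of arrays, it was 61.3, 62.8, 64.3, 63.2, 73.3 and 74.5, so these spots set the level of dim signals, but the differences were not refitted without them. The reversed log2 differences were Ccnb1 -0.87, Rnf186 -0.87, Brca1 -1.15, E2f1 -0.55, Capsl -0.67, Foxa1 -0.71, Tff2 -0.54, Tsc22d3 0.054, Sgk1 0.16, Klf9 0.13, Myh6 0.25, Nppb 0.10, Per1 0.056, Klf15 0.26, Scnn1a -0.22, Myom1 0.015, Tnni3 0.089, Cxcl10 -0.34, Cox6a2 0.043, Ndufa4 0.11, Ldhb 0.16, Gpx3 0.026, Dcn 0.099, Gsn 0.11, Dntt -0.56, Cd3g -0.79 and Itga2b -0.055, of which Ccnb1, Rnf186, Brca1 and Cd3g passed the threshold. The direction of the set test turned for these lists, given with their medians: glucocorticoid-induced genes 0.056, fetal and hypertrophy genes -0.091, calcium handling 0.18, sarcomere 0.23, ion channels and conduction 0.0084, adrenergic signalling 0.095, extracellular matrix and fibrosis 0.048, inflammatory cytokines and adhesion molecules -0.16, fatty acid oxidation 0.33, oxidative phosphorylation 0.25, glucose uptake and glycolysis 0.29, circadian clock 0.11, protein degradation and autophagy 0.31, endothelial markers 0.15, smooth muscle and pericyte markers 0.32, fibroblast and epicardial markers 0.11, macrophage and myeloid markers 0.11, lymphocyte markers -0.55 and neural and Schwann cell markers -0.65. Of these, sarcomere (adjusted p = 0.0011), fatty acid oxidation (0.00067), oxidative phosphorylation (0.00057), glucose uptake and glycolysis (0.00057), protein degradation and autophagy (0.00067) and smooth muscle and pericyte markers (0.046) passed in the turned direction. Without a turn, the heat shock (0.00090), oxidative stress (0.0017) and erythroid lists (0.046) newly passed, and the proliferation (0.126), atrial (0.253) and immediate early lists (0.183) no longer did.

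The slide as a fixed block turned the direction of the gene difference or of the set test, given with the log2 difference or the list median, for Nr3c1 -0.079, Per1 0.26, Klf15 0.14 and S100b -0.17, and for the lists calcium handling 0.13, inflammatory cytokines and adhesion molecules 0.012, fatty acid oxidation 0.11, oxidative phosphorylation 0.014, glucose uptake and glycolysis 0.021, circadian clock 0.075, protein degradation and autophagy 0.13, apoptosis and survival 0.0063, adipocyte markers 0.040 and neural and Schwann cell markers -0.26. Within slide 1 it turned for Nr3c1 -0.079, Per1 0.26, Klf15 0.14 and S100b -0.17, and for the lists calcium handling 0.13, inflammatory cytokines and adhesion molecules 0.012, fatty acid oxidation 0.11, protein degradation and autophagy 0.13, apoptosis and survival 0.0063, adipocyte markers 0.040 and neural and Schwann cell markers -0.26. With the mean of the probes of a gene it turned for Nr3c1 -0.24, Klf15 0.13, Glul -0.031 and Tek 0.013, and for the list protein degradation and autophagy -0.010. Array weights turned Per1 0.15 and the lists circadian clock 0.12 and protein degradation and autophagy -0.031. Quantile normalization turned Myh6 0.0039 and the lists glucose uptake and glycolysis 0.014 and protein degradation and autophagy 0.062. Normexp on the negative control spots turned Klf15 0.0046 and the list protein degradation and autophagy 0.020. Without a filter on dim probes the set test turned for circadian clock 0.074 and protein degradation and autophagy -0.0025, and with fry for circadian clock 0.065 and protein degradation and autophagy 0.0053. The list protein degradation and autophagy 0.033 turned with every probe tested, the same list (0.0053) with probes above background on all 6 arrays, and again (0.0053) with a variance trend. Apart from the neural and Schwann cell markers with the slide as a block and within slide 1, none of the turned results of this paragraph passed the threshold in that alternative, and the cause was not tested. With an array left out, these results changed sign in the gene fit or the set test, with lowest and highest log2 difference or median: Nr3c2 -0.72 to 0.064, Klf15 -0.075 to 0.10, inflammatory cytokines and adhesion molecules -0.048 to 0.12, heat shock and unfolded protein response -0.019 to 0.048, neural and Schwann cell markers -0.050 to 0.22, Per1 -0.28 to 0.12, circadian clock -0.033 to 0.094, oxidative stress response 0.0090 to 0.13, protein degradation and autophagy -0.046 to 0.019, apoptosis and survival -0.049 to 0.066, steroid receptors and renin-angiotensin genes -0.096 to 0.10 and Nr3c1 -0.081 to 0.15.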

Other observations

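The slide comparisons for the kallikreins and for the proliferation genes were chosen only after their results were seen, and the genes in the first paragraph were chosen after their values were seen. At an adjusted p under 0.1 in limma, 23 genes were higher and 11 lower in adrenalectomized hearts. The 23 were not all genes of cell division, and included Bdh1 at 0.95, Prnd at 1.38, Acox2 at 1.49, Igfals at 0.93 and S1pr4 at 0.79. Nuf2 and Spc25, subunits of the kinetochore complex that binds microtubules, differed by 0.87 (SE 0.10, adjusted p = 0.0587) and 1.17 (SE 0.16, adjusted p = 0.0918). Cdca8 (borealin, of the chromosomal passenger complex) differed by 1.10, Ccnb2 (cyclin B2) by 0.93, Kif20a (a kinesin of cytokinesis) by 0.74 and Cdca3 by 1.18, while Nek2, a centrosome kinase, was at least 1.70-fold higher.

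On the lower side, the calcium channel subunit gene Cacna2d1 differed by -0.96 (SE 0.11, adjusted p = 0.0587), Ramp1, part of the receptor for calcitonin gene-related peptide, by -0.95 (SE 0.13, adjusted p = 0.0860), and the adenylyl cyclase gene Adcy1 by -1.06 (SE 0.14, adjusted p = 0.0898). Of the other kallikreins measured, Klk1 differed by 0.02 (adjusted p = 0.970), Klk1b3 by -0.19 (adjusted p = 0.609) and Klk1b8 by 0.17 (adjusted p = 0.726).

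Egfbp2, Klk1b16, Klk1b26 and Klk1b5 were lower, and salivary gland tissue in the sham samples, a rich source of kallikreins, is argued against: 6 measured gland markers had a median of 0.19 (95% bootstrap interval -0.17 to 0.83), against a kallikrein median of -1.72 with bounds, with Lpo at 0.11, Egf at -0.22 and Amy1 at 0.27. Cross-hybridisation between near-identical copies cannot be told apart from a fall of several genes: 0 of the 4 probes share at least 30 bases in a row with another (longest run 9), but the Klk1b26 and Egfbp2 probes lie 45 bases apart on mm7 and may read the same transcript, so the absence of shared sequence, set beforehand as the evidence against, was the wrong criterion. The slide stays open because only 1 adrenalectomized array lies with the sham arrays, and its mean difference over the 4 genes, with bounds for Klk1b16 and Klk1b26, was -1.66, against -1.94 on slide 2. Loss of adrenal hormones is a candidate explanation that the design names and that remains untested apart from these.

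All 12 measured proliferation genes were higher, but 1 passed over all genes, and the camera call was lost with an estimated correlation (adjusted p = 0.386). For this list, a general lift of dim genes on the adrenalectomized arrays is argued against: the list median of 0.61 lay above 0.185, the upper end of the central 95% of medians of 10000 random lists matched on mean level. Thymus tissue, which is rich in dividing cells and lies next to the heart, cannot be told apart: 15 thymocyte markers had a median of 0.25 (95% bootstrap interval -0.13 to 0.50), whose upper end reaches past the level such tissue would need, with Dntt at 0.86, Lck at 0.70, Cd3e at -0.22 and Satb1 at -0.38. The slide stays open for the same reason as above, with a median of 0.56 on the adrenalectomized array of slide 1 and 0.52 on slide 2, where Ccnb1 is at its bound. More dividing cells after adrenalectomy remain an untested hypothesis.

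The lower atrial genes may reflect a smaller share of atrium in the adrenalectomized samples, which depends on how each heart was trimmed. Among Nppa, Myl4, Myl7, Sln and Bmp10, the differences spanned 0.868, more than 0.424, the range set for a like fall. No 2 of them differed by more than 2.07 standard errors when the errors of 2 genes were combined as independent. The genes were read on the same arrays, and sham replicate 2 was the highest for each, so their errors are linked and this criterion cannot decide. A smaller share of atrium thus cannot be told apart from separate regulation. Slide stays open here too, with a median of -0.57 on the adrenalectomized array of slide 1 and -0.64 on slide 2. An effect of adrenalectomy on atrial genes remains open and untested.

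The 6 arrays can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 7 genes and the highest of the other splits 0, so 1 of the 10 splits gave as many, while at an unadjusted p under 0.05 another split gave 2158 genes against 2078. For the gene lists, 2 of the 10 splits gave as many as the real split, with 12 lists each, and the highest of the others, also 12, set sham replicate 1 with adrenalectomized replicates 2 and 3. That split keeps the 2 arrays of slide 2 together, and with the slide as a block the real comparison gave 7 lists.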
